A study of Homo sapiens with 116 samples.

How the data were processed

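Polyadenylated RNA of microglia-like cells was measured by bulk sequencing in a single count table with 1 column per library, 62750 genes and 26 groups. Groups, exp numbers and replicate numbers were taken from the sample titles, and the count columns were joined to them by the library names, per the labels. No library was left out, and no part of the replicate numbers was used to pair libraries.

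The gene counts as deposited were made with cutadapt, STAR, Picard and HTSeq on build hg38, per the submitters' processing notes. Their versions, order, annotation release and strand setting are not given in the sources used here. The deposited values were whole numbers, read as raw counts. The log2 fold changes and their SE in the results table were computed by the authors with DESeq2 for genes within 200 kb of each guide region, per the file name. The p-values and the FDR-adjusted p-values in that table, over all genes and renewed within those genes, were also computed by the authors with DESeq2, per the file headers. Its design, reference libraries and filters are not given in the sources used here. The guide regions, each 1000 bp wide, were taken from the same table and set against the 5' ends of genes in GENCODE release 29.

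Totals ran from 1593444 to 38288269 counts per library. Genes passed edgeR filterByExpr with the groups, and the genes named in the titles were kept whatever their counts, which left 21573 genes with 99.98% of the counts. The fit was edgeR 4.0.16 quasi-likelihood in R 4.3.3 with TMM factors, a term for each group and the exp number as a factor, giving 31 design columns and 85 residual degrees of freedom. Each guide group was contrasted with the SafeHarbor control, and each of 14 pairs of a variant and a gene with the promoter group of that gene. Exp 5 and exp 6 hold no control, so their libraries reach the control only through groups that also lie in other exps. P was adjusted by the Benjamini-Hochberg method over all genes of a comparison with a threshold of 0.05. It was also adjusted over the 23 tests of targeted genes alone, the 14 differences alone, and the nearby genes of each comparison alone. The nearby genes were those the authors listed for a comparison, 2 to 18 of them, and not every gene within 200 kb. The SE was the absolute log2 fold change over the square root of F, which is approximate. CPM values are counts over the library total times its TMM factor, with the exp effects left in.

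Named genes followed a rule fixed before the data were examined. It took the targeted genes, the nearby genes with adjusted p under 0.05 over the nearby genes alone, and the 3 largest rises and 3 largest falls past the threshold. These needed an average log2 CPM of at least 1, the same sign against all other loci's libraries and a symbol that is not a clone name. For the 2 promoter and 2 variant groups with most genes changed, 10 rises and 10 falls were taken. Of each list past the threshold, up to 4 members with the smallest p were taken, and the text prints part of all these. ANXA4 and its neighbours, and the genes that differ between the control and all guide libraries, were looked at after their values were seen.

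The 31 gene lists (603 genes) were fixed before the data were examined. They were homeostatic microglia, myeloid identity, disease-associated microglia, interferon response, NF-kB inflammatory response, MHC class II, MHC class I, cholesterol synthesis, LXR targets and lipid efflux, lysosome, and phagocytosis and Fc receptors. Also fixed were complement, actin and focal adhesion, endocytosis and membrane trafficking, exocyst complex, cohesin and meiosis, ephrin signalling, extracellular matrix proteases, Alzheimer risk loci genes, p53 response, and integrated stress and unfolded protein response. The others were glycolysis and hypoxia, cell cycle, pluripotent stem cell, neuron, fibroblast and mesenchyme, endothelium and blood progenitors, granulocyte and mast cell, mitochondrially encoded genes, microglia-inducing transcription factors, and immediate early genes. They were tested with limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with the correlation estimated per list. Adjustment was over all lists and comparisons.

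The alternatives were size factors by the median of ratios, no filter, no exp term, a replicate block, summed libraries, the other loci's libraries as reference, DESeq2 1.42.0, no exp 5 and exp 6, and no control libraries of each exp in turn. Each library of the groups of up to 5 was also left out in turn. Leaving out 6 libraries that correlated with their exp less than 0.947 (5 median absolute deviations below the median), and adding 3 surrogate variables from sva 3.50.0, were added later. The fit was tested on simulated data with a dispersion of 0.1 for every gene, in which 200 of 21573 genes changed. The changed genes were drawn from well-counted ones, and no exp effects or libraries standing apart were simulated. In a group of 4, 34% of 100 changes of 2-fold and 100% of 100 changes of 4-fold were recovered, and 8 of 21373 unchanged genes were called. Among 220 pairs of libraries of a group, 0 were identical, and the lowest chi-square per degree of freedom between 2 libraries was 4.86. Figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.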

Results

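The series measured polyadenylated RNA by bulk sequencing in microglia-like cells made from KOLF2.1J, an established line of human induced pluripotent stem cells with inducible transcription factors. Guide RNAs delivered by lentivirus brought a CRISPR interference repressor, which lowers transcription at the site it binds, to loci associated with Alzheimer's disease. The guides of 11 groups (52 libraries) were labelled with the promoter of a named gene, and those of 14 groups (56 libraries) with a variant and the gene or genes thought to be controlled by it. The SafeHarbor control, with guides aimed at a site chosen for having no target gene, had 8 libraries. The libraries came from 6 runs of the experiment, written here as exp 3 to exp 8, and a guide group held 3 to 8 libraries. Exp 3, 4, 7 and 8 each held 2 control libraries, while exp 5 and exp 6 held 0. Total counts per library ran from 1593444 to 38288269 with a median of 20140527, and 2 libraries had fewer than 6000000 counts. Levels are in CPM, a library's counts scaled to its total times its TMM factor, with their SD, and log2 fold changes carry their approximate SE from the edgeR fit. The labels do not say whether replicates of 1 exp were separate cultures, so the spread between them may be technical in part.

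The first comparison asked whether guides at a promoter lowered the gene in their label. BIN1, which encodes a membrane-bending adaptor used in endocytosis, fell from 185 ± 46.3 CPM in the control (n = 8) to 50.8 ± 27.4 CPM in the libraries labelled BIN1 promoter (n = 5), a log2 fold change of -1.91 ± 0.23 with adjusted p = 6.6e-09. ZNF594, a zinc finger gene, fell from 8.74 ± 1.97 CPM to 0.332 ± 0.546 CPM in the libraries labelled ZNF594 promoter (n = 4), a log2 fold change of -4.79 ± 0.49 with adjusted p = 3.9e-12. All 5 BIN1 and all 4 ZNF594 libraries lay below the lowest control library. GPC2, a glypican gene on the strand opposite STAG3, fell from 7.68 ± 2.21 to 1.13 ± 0.990 CPM in the libraries labelled STAG3 promoter (n = 5, log2 fold change -2.73 ± 0.34, adjusted p = 1.0e-08). STAG3, a subunit of the meiotic cohesin complex, was at 1.08 ± 0.518 CPM in the same libraries, with a log2 fold change of 0.01 ± 0.46 and adjusted p = 0.989 over the list alone. The STAG3 guide region (chromosome 7, 100177215 to 100178214, hg38) held the annotated 5' ends of both genes, STAG3 at 100177563 and GPC2 at 100177372.

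APOE, which encodes the main lipid carrier of the brain, stood at 671 ± 345 CPM in the libraries labelled APOE promoter (n = 8) against 1175 ± 455 CPM in the control. Its log2 fold change of -0.94 ± 0.29 had adjusted p = 0.0841 over all 21573 genes tested and 0.00664 adjusted over the list alone, that is over the 23 tests of targeted genes, and 5 of the 8 libraries lay below the lowest control. HLA-DRB1, which encodes an MHC class II chain, was at 0.954 ± 1.88 CPM in its promoter libraries (n = 5) against 2.50 ± 1.49 CPM, with a log2 fold change of -1.74 ± 0.57 and adjusted p = 0.130 over all genes and 0.00918 adjusted over the list alone. Without the HLA-DRB1 promoter library of exp 5, replicate 2, that log2 fold change was -4.58 with adjusted p = 0.0033, the lowest value with any 1 library of the group left out, and the highest was 0.572. Counting can divide reads between HLA-DRB1 and its close relative HLA-DRB5, and likewise between FCGR3B and FCGR3A, so the levels of these genes are uncertain. FCGR3B, a neutrophil Fc receptor, had 3 counts over its 4 promoter libraries, all in 1 library, and 45 over the control. Its test gave adjusted p = 0.798. ADAMTS4, a matrix protease, had 13 counts over its 6 promoter libraries and 4 over the control, with adjusted p = 0.551. SPDYE3 and EXOC3L2 had 0 counts in every library of the series. Among 2263556103 counts this allows up to 0.00133 CPM, provided that reads from these genes could be counted, which was not tested. No change in them could be detected.

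**Figure D1:**
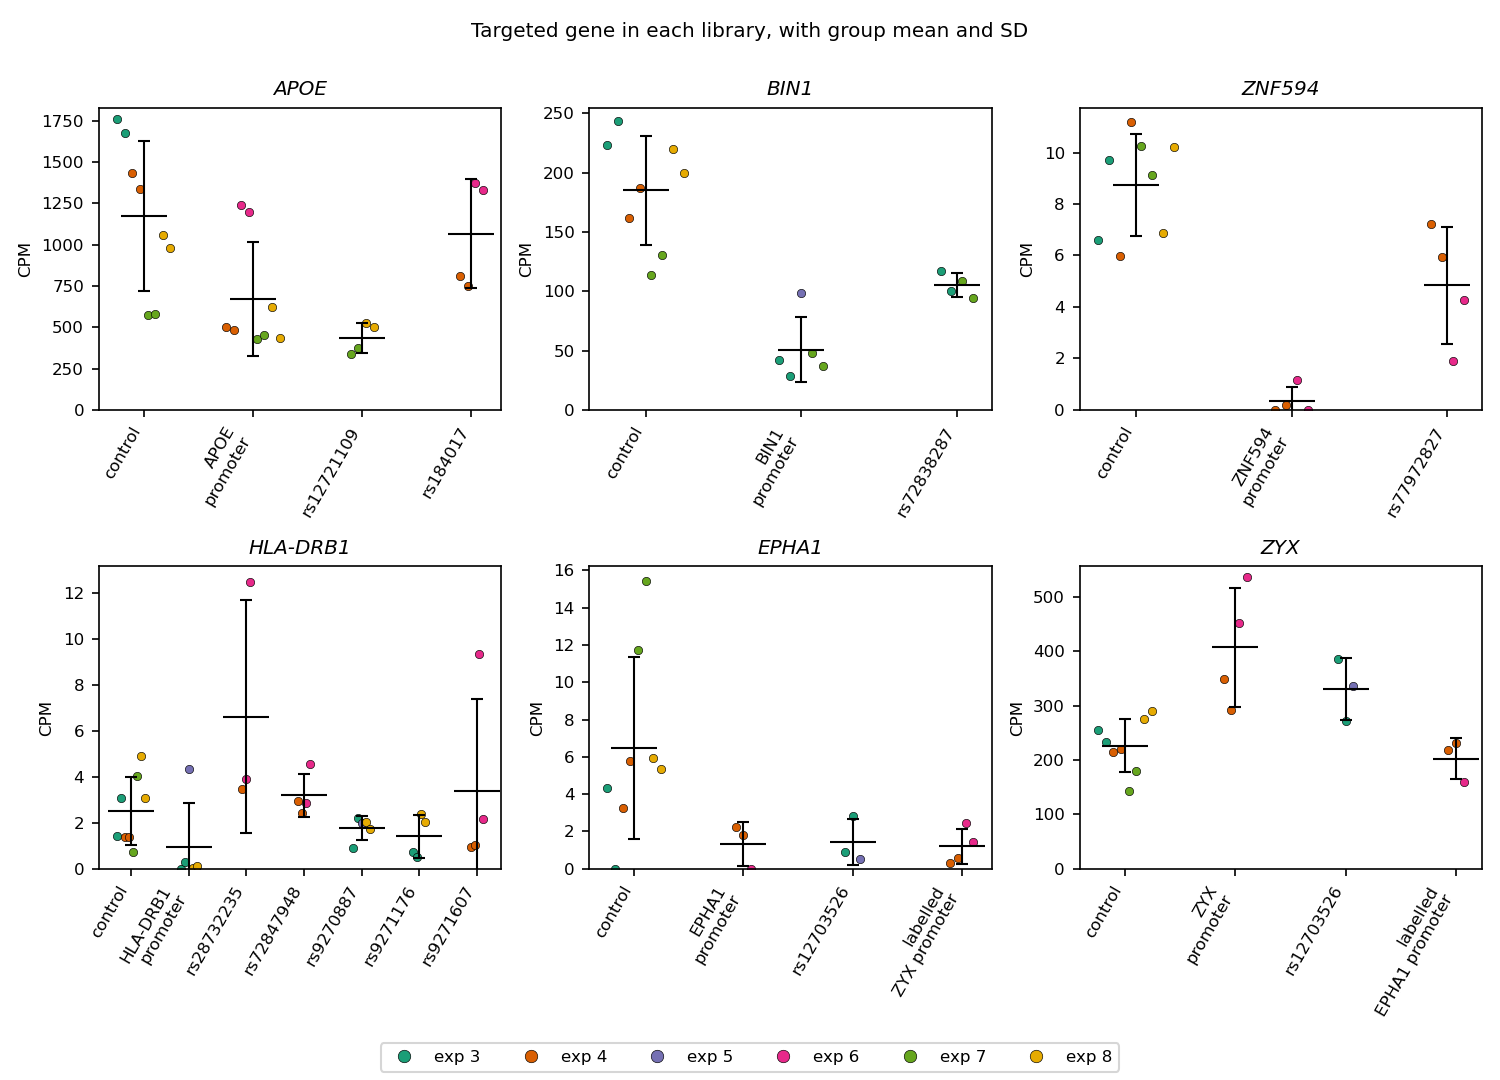
Level of 6 targeted genes in CPM (vertical axis, starting at 0) in the control libraries, the promoter libraries and the variant libraries of each locus. Each point is a library coloured by exp number, and the bars are the mean and SD; ZNF594 promoter libraries sit at 0.332 ± 0.546 CPM against 8.74 ± 1.97 CPM in the control.

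At the EPHA1 and ZYX locus, EPHA1 was lower and ZYX higher in the libraries named after ZYX. In the libraries labelled ZYX promoter (n = 4), ZYX, which encodes the focal adhesion protein zyxin, rose from 227 ± 48.4 to 407 ± 109 CPM (log2 fold change 0.76 ± 0.18, adjusted p = 0.00759). EPHA1, an ephrin receptor, was at 1.19 ± 0.960 CPM in the same libraries against 6.48 ± 4.89 CPM in the control, with a log2 fold change of -1.62 ± 0.55 and adjusted p = 0.0598 over all genes and 0.00961 over the 5 nearby genes alone. In the libraries labelled EPHA1 promoter (n = 3), EPHA1 was at 1.34 ± 1.18 CPM (log2 fold change -0.87 ± 0.59, adjusted p = 0.524) and ZYX at 203 CPM (160 to 231 CPM in single libraries). The deposited region named EPHA1 promoter (chromosome 7, 143380753 to 143381752) held the annotated 5' end of ZYX at 143381080 and lay 27140 bp from that of EPHA1. The region named ZYX promoter (143408630 to 143409629) held the 5' end of EPHA1 at 143408892 and lay 27550 bp from that of ZYX. The other 9 promoter regions lay within 1000 bp of the 5' end of the gene in their label. Against the other loci's libraries of the same exp, EPHA1 in the libraries labelled ZYX promoter fell by 3.00 ± 0.88 on the log2 scale in exp 4 (adjusted p = 0.0060 over the list alone) and had a log2 fold change of -0.87 ± 0.63 in exp 6 (adjusted p = 0.303). ZYX in the libraries labelled EPHA1 promoter had a log2 fold change of -0.37 ± 0.25 in exp 4 (adjusted p = 0.269). Their single exp 6 library, of 1593444 counts with 7661 genes detected, stood apart from its exp. The rise of ZYX was no longer past the threshold against the other loci's libraries, at 0.45 with adjusted p = 0.189, where 14 alternatives ranged from 2.7e-04 to 0.189.

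**Figure D2:**
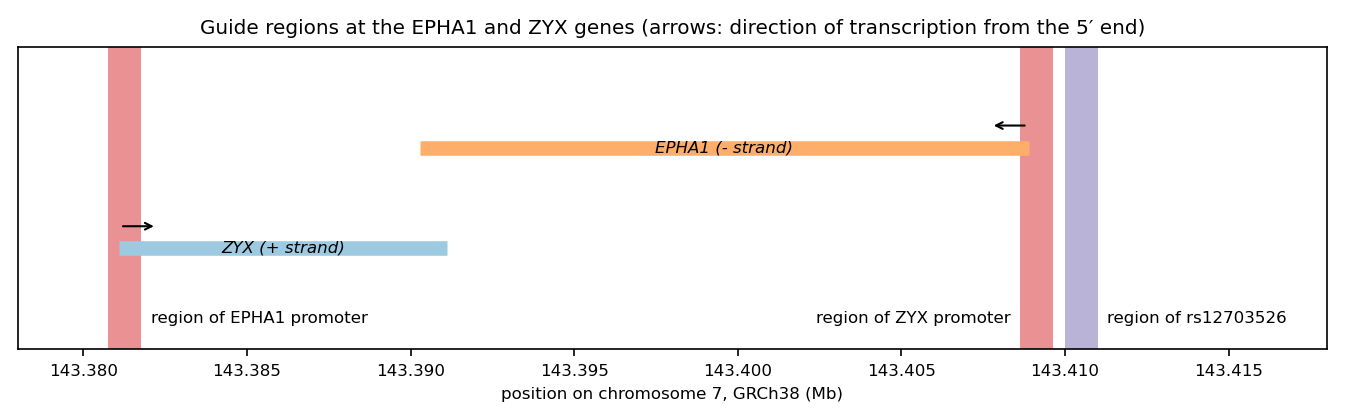
Map of chromosome 7 (hg38, position in megabases on the horizontal axis) with EPHA1 and ZYX drawn as arrows and the guide regions named EPHA1 promoter, ZYX promoter and rs12703526 as bars. The region named EPHA1 promoter lies on the 5' end of ZYX, 27140 bp from that of EPHA1, and the region named ZYX promoter lies on the 5' end of EPHA1.

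The second comparison asked whether guides at a variant lowered the gene named with it. At the APOE locus, guides at rs12721109, in an intron of APOC4, went with lower APOC1 and APOE, both genes of lipoproteins. APOC1 was at 16.6 ± 1.96 CPM (n = 4) against 45.8 ± 10.7 CPM in the control (log2 fold change -1.50 ± 0.42, adjusted p = 0.109 over all genes and 0.00548 over the nearby genes alone). APOE was at 435 ± 92.8 CPM (log2 fold change -1.14 ± 0.38, adjusted p = 0.195 over all genes and 0.0176 over the nearby genes alone), and every one of the 4 libraries lay below the lowest control for both genes. Guides at rs184017, in an intron of TOMM40, lowered TOMM40, which encodes the import channel of the outer mitochondrial membrane, from 35.4 ± 6.18 to 21.9 ± 12.2 CPM (n = 4, log2 fold change -0.98 ± 0.21, adjusted p = 0.0262). That region held an annotated 5' end of TOMM40. APOE there was at 1067 ± 332 CPM (log2 fold change -0.52 ± 0.38, adjusted p = 0.874 over all genes and 0.230 adjusted over the list alone). Within exp 4, the exp of this group that held controls, APOE was at 781 against 1386 CPM. The authors' deposited value for APOE there was -0.54 ± 0.20, with a renewed adjusted p of 0.0463 in DESeq2. At the BIN1 locus, rs72838287 lies 27525 bp from the 5' end of BIN1, and BIN1 was at 105 ± 9.93 CPM there (n = 4, log2 fold change -0.77 ± 0.23, adjusted p = 0.588 over all genes and 0.00616 adjusted over the list alone).

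With guides at rs77972827, in an exon of SCIMP, ZNF594 was lower, at 4.83 ± 2.29 CPM (n = 4, log2 fold change -1.04 ± 0.31, adjusted p = 0.0123), and USP6, a deubiquitinase gene, was at 36.4 ± 17.4 against 58.7 ± 7.18 CPM (log2 fold change -0.84 ± 0.23, adjusted p = 0.00769). ZFP3 and RABEP1 passed over the nearby genes alone, with log2 fold changes of -0.55 ± 0.24 and -0.37 ± 0.16 and adjusted p = 0.0413 for each. Both exp 6 libraries of this group stood apart from their exp (r = 0.943 and 0.910 with its median), and USP6, ZFP3 and RABEP1 were not tested by exp. The change of ZNF594 was seen in exp 6, at -1.69 ± 0.42 against the other loci's libraries (adjusted p = 9.0e-04 over the list alone), and was -0.12 ± 0.33 in exp 4 (adjusted p = 0.818). Without exp 5 and exp 6 its log2 fold change against the control was -0.54 with adjusted p = 0.470, where 14 alternatives ranged from 0.0114 to 0.811.

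Among the MHC variants, HLA-DRB1 was higher with rs28732235, at 6.62 ± 5.09 CPM (n = 3, log2 fold change 1.38 ± 0.50, adjusted p = 0.122 over all genes and 0.0178 adjusted over the list alone), and 1 of the 3 libraries lay above the highest control. With 1 library of that group left out, the log2 fold change ran from 0.81, without exp 6 replicate 2, to 1.78. The other 4 MHC variants had HLA-DRB1 log2 fold changes between -1.08 ± 0.57 (rs9271176) and 0.62 ± 0.52 (rs9271607), with adjusted p of at least 0.107 over the list alone. At the SPDYE3 locus, rs6979218 went with lower GPC2, at 3.69 ± 0.753 CPM (n = 4, log2 fold change -0.82 ± 0.29, adjusted p = 0.163 over all genes and 0.0348 over the nearby genes alone). AP4M1, a subunit of an adaptor complex of vesicle traffic, had a log2 fold change of -0.63 ± 0.20 there, with adjusted p = 0.0268 over the nearby genes alone. With rs12703526, 1103 bp from the 5' end of EPHA1, EPHA1 was at 1.41 ± 1.24 CPM (n = 3, log2 fold change -1.28 ± 0.53, and from -2.30 to -0.94 with 1 library left out) and ZYX at 331 ± 56.9 CPM (log2 fold change 0.44 ± 0.19), with adjusted p = 0.0345 and 0.0479 over the list alone and 0.955 and 0.968 over all genes. Within exp 3, the mean log2 CPM of EPHA1 was 1.36 higher than in the control libraries, while its mean was 1.87 against 2.16 CPM. Against the other loci's libraries, the log2 fold changes with rs12703526 were -1.19 for EPHA1 and 0.13 for ZYX. With rs4575098, FCGR3B was at 0.901 ± 0.653 CPM against 0.227 ± 0.272 CPM (log2 fold change 1.89 ± 0.76, adjusted p = 0.790 over all genes and 0.0328 adjusted over the list alone). Against the other loci's libraries FCGR3B there had a log2 fold change of 0.45 (edgeR, adjusted p = 0.798). STAG3 with rs13230744 had a log2 fold change of -0.69 ± 0.54 (adjusted p = 0.574), and from -1.15 to -0.43 with 1 library left out. In all, 25 of the 192 pairs of a comparison and a nearby gene passed over the nearby genes alone, and 7 of them over all genes. These pairs were limited to the genes the authors listed, 2 to 18 per comparison. Genes closer to a guide region could be missing. SCIMP at rs77972827, HLA-DRA at 19686 bp from rs28732235 and HLA-DQA1 at 3891 bp from rs9271607 were not among them.

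The third comparison set each variant group against the promoter group of the same gene. ZNF594 was 13.5-fold higher with rs77972827 than in the libraries labelled ZNF594 promoter (log2 difference 3.75 ± 0.57, n = 4 against 4, adjusted p = 4.0e-08 adjusted over the list alone of 14 tests). With 1 library left out that log2 difference ran from 3.40 to 5.83, the most without the ZNF594 promoter library of exp 6, replicate 1. BIN1 was 2.20-fold higher with rs72838287 than in its promoter libraries (log2 difference 1.14 ± 0.25, n = 4 against 5, adjusted p = 6.1e-05). HLA-DRB1 was higher than in its promoter libraries with rs28732235 (log2 difference 3.12 ± 0.67), rs9271607 (2.37 ± 0.69) and rs72847948 (2.30 ± 0.70), with adjusted p from 6.1e-05 to 0.00347. Without the HLA-DRB1 promoter library of exp 5, replicate 2, these differences were 5.95, 5.16 and 5.12. FCGR3B was 4.36 ± 1.33 higher with rs4575098 (adjusted p = 0.00347), from 73 counts against 3, and from 3.73 to 7.33 higher with 1 library left out, the most without the promoter library that held those 3. For APOE, neither rs12721109 (log2 difference -0.19 ± 0.37, adjusted p = 0.605) nor rs184017 (0.43 ± 0.36, adjusted p = 0.305) passed, and 8 of the 14 differences in all did not. Without the rs9271607 library of exp 6, replicate 1, its HLA-DRB1 difference was 1.25 with adjusted p = 0.301, against 1.0e-05 to 0.301 with any 1 library of either group left out.

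Within the exps that held controls, 31 of 37 differences in mean log2 CPM between a group and the control had the sign of the pooled value. BIN1 in its promoter libraries differed by -2.74 in exp 3 and by -1.53 in exp 7, each from 2 libraries against 2 and without a test. APOE in its promoter libraries differed by -1.49, -0.39 and -0.97 in exp 4, 7 and 8, and HLA-DRB1 by -3.48 and -4.40 in exp 3 and 8. The deposited table of the authors' fold changes, made with DESeq2, held the same 192 pairs of a comparison and a nearby gene. The sign was shared in 154 of the 192 pairs (80.2%), and the median absolute difference in log2 fold change was 0.12. Of 15 pairs that the authors' renewed adjusted p placed under 0.05, 10 passed in the refit over the nearby genes alone. The authors' value for BIN1 in its promoter libraries was -2.01 ± 0.15, for GPC2 in the libraries labelled STAG3 promoter -2.96 ± 0.42, and for APOC1 with rs12721109 -1.30 ± 0.13. With rs77972827 their values were -0.65 ± 0.42 for ZNF594, -0.56 ± 0.34 for USP6, -0.42 ± 0.29 for ZFP3 and -0.29 ± 0.20 for RABEP1, each with a renewed adjusted p of 0.186 in DESeq2.

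The fourth comparison asked which genes changed anywhere in the genome. The largest count was in the rs77972827 libraries, with 2433 genes higher and 1593 lower. Next came the libraries labelled ZYX promoter (743 and 478) and EXOC3L2 promoter (447 and 217), then those of rs28732235 (360 and 134), rs9271607 (384 and 71) and those labelled EPHA1 promoter (390 and 22). The other 19 comparisons called 3 to 260 genes each. The 8 control libraries were shared by every comparison. A single gene, ANXA4, which encodes a calcium-dependent membrane-binding annexin, was lower in each of them (5.05 to 14.6 CPM) than in each of the 108 guide libraries (44.6 to 101 CPM). ANXA4 was thus higher than in the control in every comparison. The naming rule, which also needs the same sign against the other loci's libraries, listed it among the largest rises in 11 of them. It rose 9.02-fold in the libraries labelled APOE promoter (log2 fold change 3.17 ± 0.13, n = 8, adjusted p = 1.4e-39) and 10.2-fold with rs6979218 (3.35 ± 0.14, n = 4, adjusted p = 7.4e-37). Against the other loci's libraries these 2 log2 fold changes were 0.05 and 0.24, with adjusted p of 1.00 and 0.134. IL1RN, which encodes the interleukin 1 receptor antagonist, rose against the control too, as in the libraries labelled FCGR3B promoter from 37.8 ± 24.4 to 134 ± 30.6 CPM (n = 4, adjusted p = 6.6e-06) and with rs12721109 to 138 ± 29.5 CPM (n = 4, adjusted p = 2.5e-06). For IL1RN, however, 32 of the 108 guide libraries lay at or below the highest control. Over 14 alternatives these log2 fold changes went as low as 0.08 and 0.17, and 13 of 14 kept each call.

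**Figure D3:**
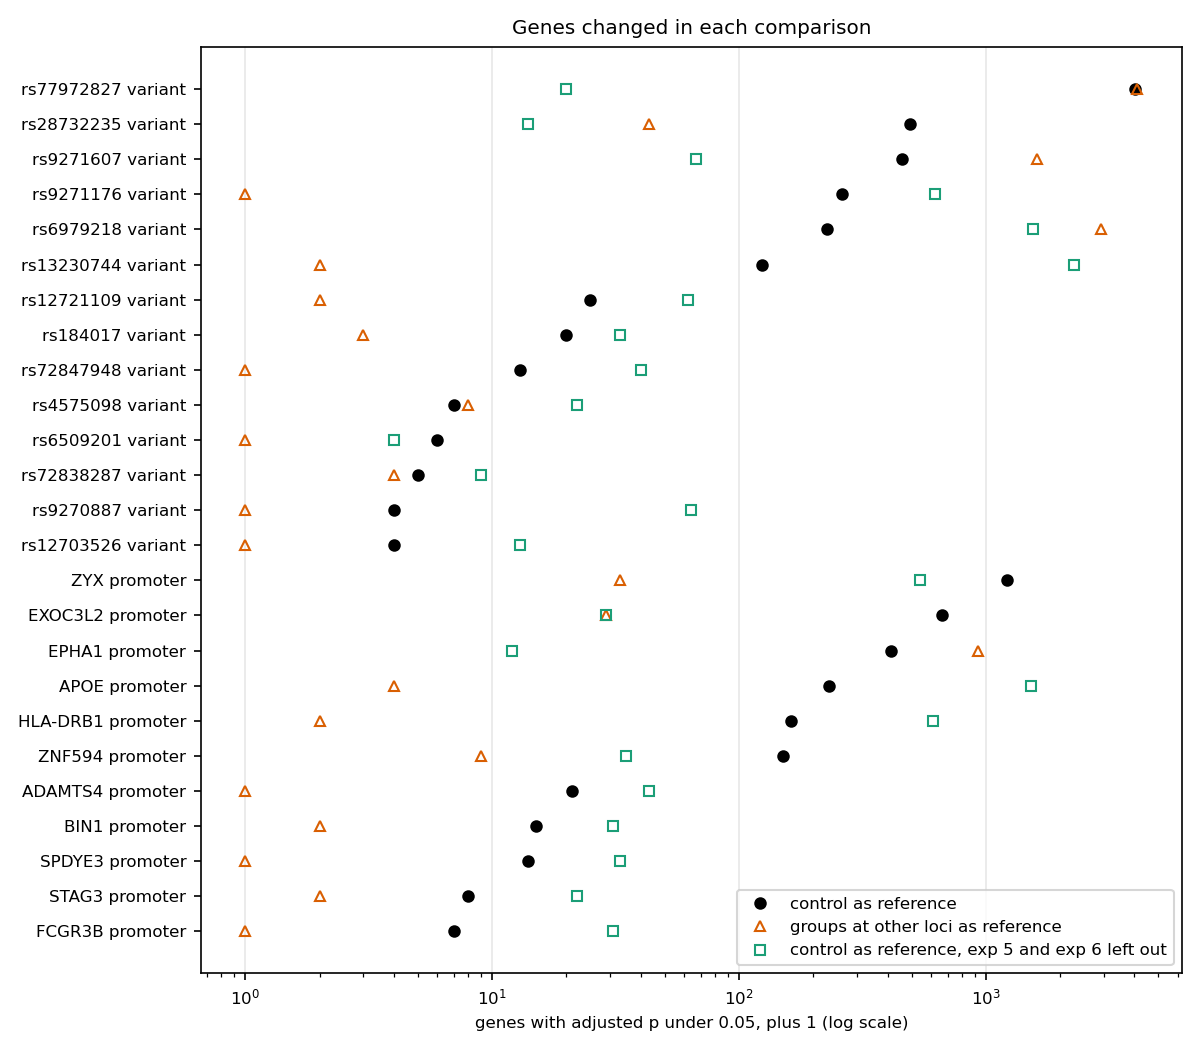
Number of genes changed plus 1 (horizontal axis, log scale) for each of the 25 guide groups, with the control libraries as reference, with the other loci's libraries as reference, and without exp 5 and exp 6. With rs77972827, 4026 genes changed against the control, 4111 against the other loci and 19 without exp 5 and exp 6.

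In the libraries labelled ZYX promoter (n = 4), some genes of dividing cells, of the actin skeleton and of myeloid identity rose. TYMS, the thymidylate synthase, rose 3.00-fold to 38.5 ± 11.5 CPM (adjusted p = 9.6e-04), and 18 of 31 cell cycle genes rose, with CDK1 4.65-fold, BIRC5 4.88-fold and PLK1 2.33-fold higher. ACTB, the cytoplasmic actin, rose from 3286 ± 964 to 6886 ± 1043 CPM (2.30-fold, adjusted p = 0.00145), and VASP, an actin polymerase at adhesions, and TPM4, a tropomyosin, rose 1.81-fold and 1.77-fold. The cell cycle list (adjusted p = 2.0e-19) and the actin and focal adhesion list, with 7 of 24 members higher (adjusted p = 2.9e-06), did not hold with an estimated correlation between genes (adjusted p = 0.583 and 0.688 with an estimated correlation). CD14, the co-receptor for lipopolysaccharide, rose from 157 ± 91.7 to 462 ± 68.6 CPM (2.92-fold, adjusted p = 0.0202). CD33, a sialic acid receptor of myeloid cells, rose 2.22-fold, FCGR2A, an Fc receptor, 2.73-fold, and CSF1R, the receptor on which microglia depend, 1.75-fold. The myeloid identity list had 6 of 17 members higher and the homeostatic microglia list 5 of 16 (adjusted p = 0.00187 and 0.00802; adjusted p = 0.759 and 0.770 with an estimated correlation).

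Other lists moved in the libraries labelled ZYX promoter as well. HLA-DPA1, an MHC class II chain, rose 2.76-fold and CD74, the class II invariant chain, 1.55-fold. LDHA, the lactate dehydrogenase of glycolysis, rose from 229 ± 37.1 to 385 ± 106 CPM (1.90-fold, adjusted p = 4.0e-05), CDKN1A, a p53 target that stops the cell cycle, 1.71-fold, and FDFT1, the squalene synthase, rose from 178 ± 28.8 to 252 ± 37.2 CPM. The lists of MHC class II (3 of 13 higher, adjusted p = 0.00540), glycolysis and hypoxia (5 of 24, 1.0e-05), p53 response (4 of 18, 1.8e-04) and cholesterol synthesis (3 of 22, 0.00448) passed, with adjusted p = 0.688, 0.583, 0.622 and 0.770 with an estimated correlation. KLF2, a transcription factor induced early after stimulation, rose 2.40-fold, and 4 of 14 immediate early genes rose (adjusted p = 0.00348; adjusted p = 0.745 with an estimated correlation). SLC7A11, the cystine importer, fell from 4.42 ± 1.66 to 0.745 ± 0.536 CPM (n = 4, adjusted p = 0.0142). COL4A1, a basement membrane collagen, fell from 64.9 ± 61.8 to 7.10 ± 7.11 CPM (adjusted p = 0.00419), and LUM, the proteoglycan lumican, from 3.42 ± 2.97 to 0.649 ± 0.531 CPM (adjusted p = 0.00994). The fibroblast and mesenchyme list fell (3 of 19 lower, adjusted p = 0.0496; adjusted p = 0.760 with an estimated correlation). All 13 mitochondrially encoded genes were lower with 0 of them past the threshold in edgeR over all genes. MT-ND5 was nearest to it at 1084 ± 464 against 1888 ± 145 CPM (unadjusted p = 0.00642 in the edgeR fit; list adjusted p = 2.0e-04; adjusted p = 0.694 with an estimated correlation). The count of 1221 genes was 14 with the libraries of a group and exp summed, 538 without exp 5 and exp 6 and 32 against the other loci's libraries.

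In the libraries labelled EXOC3L2 promoter (n = 4), some cell cycle, interferon and Fc receptor genes rose and some lysosomal genes fell, although EXOC3L2 itself was not detected. DLGAP5 and KIF18B, both needed at the mitotic spindle, rose 5.11-fold and 5.08-fold, and TPX2 rose from 13.8 ± 6.47 to 42.8 ± 23.0 CPM (2.75-fold, adjusted p = 0.0167), among 11 of 31 cell cycle genes. CMPK2, an interferon-induced kinase, rose 2.62-fold (adjusted p = 0.0115) and MX2, an antiviral GTPase, 1.43-fold, FCGR2B, the inhibitory Fc receptor, 3.52-fold, and ACTN1, an actin crosslinker, 1.81-fold. SQLE, the squalene epoxidase, rose from 159 ± 10.5 to 201 ± 13.9 CPM (1.66-fold, adjusted p = 0.0388) and ACAT2 2.14-fold. CTSA, a lysosomal peptidase, fell from 214 ± 36.3 to 113 ± 21.5 CPM (adjusted p = 0.00721), and MCOLN1, the lysosomal calcium channel, from 59.3 ± 6.01 to 39.3 ± 6.40 CPM (adjusted p = 0.0119). SLC7A11 fell from 4.42 ± 1.66 to 0.414 ± 0.502 CPM, ASS1, the argininosuccinate synthase, from 25.0 ± 8.82 to 4.31 ± 0.640 CPM (adjusted p = 0.0135), and CEBPA, one of the transcription factors used to induce microglia, from 5.07 ± 2.50 to 1.34 ± 0.536 CPM (adjusted p = 0.0158). The lists of cell cycle (adjusted p = 1.3e-14), interferon response (3 of 25 higher, 1.5e-04), phagocytosis and Fc receptors (4 of 18 higher, 4.9e-04), cholesterol synthesis (2 of 22 higher, 0.00160) and lysosome (3 of 24 lower, 0.0173) passed. With an estimated correlation they gave adjusted p = 0.688, 0.583, 0.688, 0.737 and 0.835. In all, 10 lists passed in this group with the preset correlation, 7 higher and 3 lower, of which those above are a part. The count of 664 genes was 3 with the libraries of a group and exp summed, 121 without the library of exp 6, replicate 2, and 28 against the other loci's libraries.

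In the rs77972827 libraries (n = 4), the largest named rises were RETN, which encodes the myeloid protein resistin, to 38.8 ± 41.8 CPM (14.9-fold, adjusted p = 2.8e-06), and S100A4, a calcium-binding protein, from 59.5 ± 38.3 to 907 ± 848 CPM (7.60-fold, adjusted p = 5.9e-04). S100A9 and S100A8, the calprotectin subunits of neutrophils and monocytes, rose 5.66-fold and 3.74-fold, although S100A8 turned to a log2 fold change of -0.31 without exp 5 and exp 6. The granulocyte and mast cell list had 4 of 9 members higher (adjusted p = 0.0241; adjusted p = 0.651 with an estimated correlation). BAX and FDXR, both p53 targets, rose 2.33-fold and 3.36-fold among 8 of 18 p53 response genes (adjusted p = 0.00270; adjusted p = 0.688 with an estimated correlation). PKM and ENO1, glycolytic enzymes, rose 2.14-fold and 2.28-fold, and ACTB, TAGLN2 and ZYX 2.42-fold, 2.53-fold and 1.95-fold. MCM5, MCM7 and E2F1, genes of DNA replication, rose 2.47-fold, 2.65-fold and 3.62-fold. AIF1, which encodes the microglial protein IBA1, rose from 109 ± 31.8 to 236 ± 158 CPM (2.28-fold, adjusted p = 0.00196). CPT1A, the gate of mitochondrial fatty acid oxidation, fell from 37.2 ± 24.1 to 7.64 ± 7.48 CPM (adjusted p = 0.00386). In 2 of the 4 libraries, those of exp 6, the profile stood apart from the rest of its exp, with 16231 and 14290 genes detected against 20169 and 21164 in exp 4. Several of these genes exceeded the highest control in 2 of 4 libraries, as S100A9, MCM5 and AIF1 did. Without exp 5 and exp 6 the count of 4026 genes was 19, without the libraries that stood apart it was 15, and with the libraries of a group and exp summed 1495.

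In the rs28732235 libraries (n = 3), 3 of 25 interferon response genes and 3 of 13 MHC class II genes rose. OASL and OAS1, sensors of double-stranded RNA induced by interferon, rose 5.96-fold and 3.03-fold (adjusted p = 5.4e-04 and 0.0152), and MX1 rose from 70.8 ± 41.5 to 195 ± 133 CPM (2.15-fold, adjusted p = 0.0396). HLA-DPA1 rose 2.54-fold and CD74 1.58-fold. The lists of interferon response (3 of 25 higher, adjusted p = 1.3e-05) and MHC class II (3 of 13 higher, adjusted p = 0.00225) gave adjusted p = 0.583 and 0.682 with an estimated correlation. PHOX2A, a transcription factor of autonomic neurons, rose from 1.93 ± 0.811 to 11.3 ± 8.52 CPM (6.40-fold, adjusted p = 1.5e-05), and TYRO3, a receptor for apoptotic cells, 2.10-fold. PTPRN fell from 21.3 ± 10.9 to 7.03 ± 1.37 CPM (adjusted p = 0.0221) and SLC7A11 to 0.676 ± 0.682 CPM (adjusted p = 0.0215). The count of 494 genes was 26 with the libraries of a group and exp summed, 29 without the library of exp 6, replicate 2, 13 without exp 5 and exp 6, and 42 against the other loci.

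The remaining comparisons had fewer changes or rested on single libraries. With rs9271607 (n = 4), FASN, the fatty acid synthase, fell from 312 ± 64.1 to 186 ± 60.1 CPM (adjusted p = 0.00906). INSIG1, a sensor of sterols, fell from 98.4 ± 24.6 to 49.9 ± 35.6 CPM (adjusted p = 0.0463). The cholesterol synthesis list fell there (1 of 22 members past the threshold and 19 with a negative log2 fold change, adjusted p = 2.2e-04; adjusted p = 0.688 with an estimated correlation). The count of 455 genes was 5 without the library of exp 6, replicate 1, which stood apart from its exp (r = 0.884 with its median, 14207 genes detected). With guides labelled EPHA1 promoter (n = 3), CRABP1, a retinoic acid carrier, and SV2C, a synaptic vesicle protein, rose 17.0-fold and 9.07-fold, yet in 1 of 3 libraries above the highest control. Without the exp 6 library of 1593444 counts the count of 412 genes was 3. With rs9271176 (n = 4), HMOX1, the haem oxygenase, fell from 3150 ± 1140 to 977 ± 186 CPM (adjusted p = 0.00124). EDN1, the vasoconstrictor endothelin, rose 8.72-fold, CCL4, a chemokine, 4.45-fold and IL1A, an interleukin, 2.60-fold. The NF-kB list had 6 of 25 members higher (adjusted p = 2.2e-04; adjusted p = 0.705 with an estimated correlation). Against the other loci's libraries 0 of its genes passed in edgeR, where 1111 had an unadjusted p under 0.05, in place of 260. TNF, a central inflammatory cytokine, in the libraries labelled APOE promoter (n = 8) rose from 21.5 ± 12.3 to 64.1 ± 24.6 CPM (2.44-fold, adjusted p = 0.00332), CCL2 2.39-fold and EGR3 2.73-fold. HOXB7 fell from 7.07 ± 6.87 to 1.77 ± 2.38 CPM (adjusted p = 0.00761). None of these 4 genes passed against the other loci's libraries, where the count of 231 genes was 3, or without the control libraries of exp 4, where it was 7. CAPN6, a calpain of the cytoskeleton, in the libraries labelled HLA-DRB1 promoter (n = 5) rose from 0.797 ± 0.660 to 11.5 ± 4.07 CPM (16.1-fold, adjusted p = 8.3e-11) and also stood 1.74 higher on the log2 scale than in the other loci's libraries (adjusted p = 3.0e-04). With rs6979218 (n = 4), the mitochondrially encoded genes were higher as a list (12 of 13 with a positive log2 fold change, which counts signs and not calls, adjusted p = 1.4e-04; adjusted p = 0.688 with an estimated correlation), with MT-CO1 at 7417 ± 1205 against 6083 ± 688 CPM. Its library of exp 8, replicate 2, with 16883 genes detected, stood apart from its exp. RETN in the libraries labelled ZNF594 promoter (n = 4) rose 8.34-fold (adjusted p = 0.00299) and S100A9 4.21-fold (adjusted p = 0.0157). The rise of RETN was not confined to the ZNF594 locus. With the MHC variant rs28732235 its log2 fold change was 1.35 to 3.87 over 14 alternatives, of which 13 kept the call. In the libraries labelled ZNF594 promoter the count of 150 genes was 5 without the library of exp 6, replicate 2, which stood apart from its exp (r = 0.935 with its median, 16111 genes detected).

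The fifth comparison tested 31 gene lists fixed beforehand in each of the 25 comparisons. Of 775 tests, 173 passed with the preset correlation of 0.01, and 0 passed with the correlation estimated per list in limma camera, where 50 had an unadjusted p under 0.05 and the lowest adjusted p was 0.583. The cell cycle list rose in 21 comparisons and fell in 1, actin and focal adhesion rose in 20, immediate early genes in 17, phagocytosis and Fc receptors in 13, and glycolysis and hypoxia in 10. Against the other loci's libraries the first 4 of these lists rose past the threshold in 9 of those 21, 5 of 20, 2 of 17 and 4 of 13 comparisons, and cell cycle fell past it in 3 of the 21. Myeloid identity and MHC class II rose in 9 each, NF-kB inflammatory response in 8, p53 response and the granulocyte and mast cell list in 7 each, extracellular matrix proteases in 4, homeostatic microglia in 3 and disease-associated microglia in 1. Interferon response rose in 8 and fell in 1, MHC class I rose in 4 and fell in 1, cholesterol synthesis rose in 3 and fell in 3, and integrated stress and unfolded protein response rose in 2 and fell in 2. Lysosome rose in 1 and fell in 6, mitochondrially encoded genes rose in 1 and fell in 5, and LXR targets and lipid efflux, fibroblast and mesenchyme, and the microglia-inducing transcription factors fell in 2 each. Complement, endocytosis and membrane trafficking, exocyst complex, cohesin and meiosis, and ephrin signalling passed in 0 comparisons, with lowest adjusted p of 0.0830, 0.0511, 0.282, 0.0864 and 0.131 and 1, 3, 0, 2 and 2 comparisons at an unadjusted p under 0.05. The genes of Alzheimer risk loci and the lists of pluripotent stem cell, neuron, and endothelium and blood progenitors also passed in 0, with lowest adjusted p of 0.115, 0.101, 0.111 and 0.119 and 2, 1, 1 and 2 comparisons at an unadjusted p under 0.05. All 25 comparisons shared the 8 control libraries, so a list that is low in those libraries is counted many times over. The libraries labelled EPHA1 promoter and those of rs4575098 had 0 lists past the threshold in limma camera, with 3 lists each at an unadjusted p under 0.05 and 0 each with the estimated correlation.

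**Figure D4:**
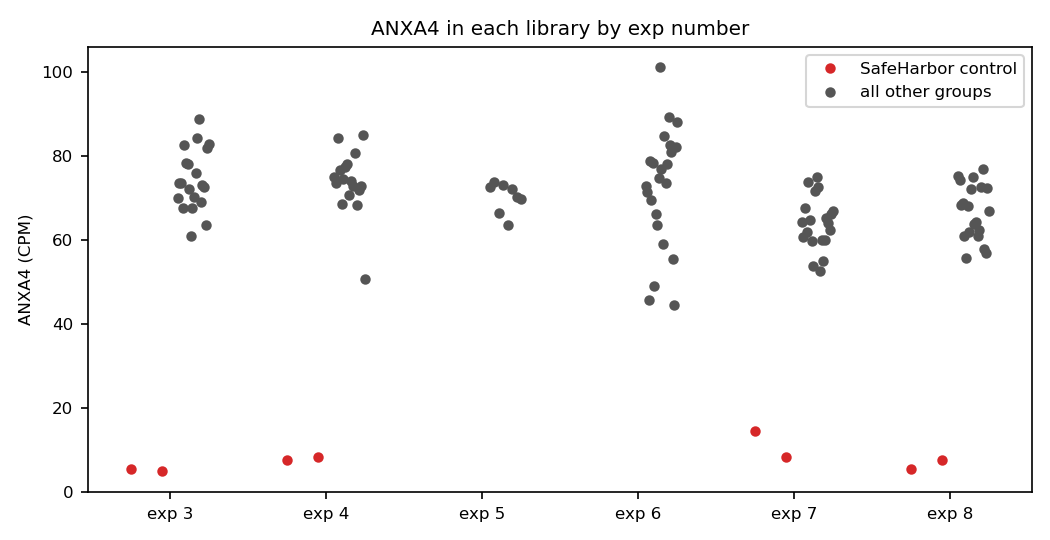
ANXA4 level in CPM (vertical axis) per library by exp number (horizontal axis), control libraries and guide libraries drawn separately. The 8 control libraries lie between 5.05 and 14.6 CPM and the 108 guide libraries between 44.6 and 101 CPM.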

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

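In this part the tests of the EPHA1 and ZYX names, of ANXA4, of depth and of ZNF594 repression were chosen after the results were seen, while the fit without exp 5 and exp 6 and the splits were set before the data were examined.

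Among 51 sets of values, 9 held a library far from the others of its group, by a bound set for about 1 in 20 sets. In 3 of the 9, FCGR3B in its promoter group and ADAMTS4 with rs4575098 and in the control, every other library was at 0, so any count reached the bound and that rate does not apply. BIN1 in its promoter group reached 98.2 CPM in exp 5, replicate 2, against 28.7 to 47.9 CPM in the other 4 libraries. HLA-DRB1 in its promoter group reached 4.32 CPM in exp 5, replicate 2, against 0 to 0.271 CPM. ZNF594 in its promoter group reached 1.14 CPM in exp 6, replicate 1, against 0 to 0.189 CPM. FCGR3B in its promoter group was at 0.172 CPM in exp 8, replicate 1, and at 0 in the other 3. HLA-DRB1 with rs9271607 reached 9.35 CPM in exp 6, replicate 1, against 0.935 to 2.16 CPM. ADAMTS4 was at 0.0838 CPM in the rs4575098 library of exp 3, replicate 1, and at 0.183 CPM in the control library of exp 7, replicate 1, and at 0 in the others of each group. Total counts were 15957098 in the rs184017 library of exp 6, replicate 2, against 21961884 to 22087851, and 12994696 in the rs6509201 library of exp 6, replicate 2, against 18866881 to 19846228.

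Of 45 differences between exps in the change of a gene, measured against the other loci's libraries, 1 passed. BIN1 in its promoter group changed by -2.65 in exp 3 and -1.04 in exp 5, a log2 difference of 1.61 ± 0.48 (edgeR, adjusted p = 0.0468 over the list alone). The exp 5 arm is the single library at 98.2 CPM given above, so its spread was taken from other groups and the difference restates that library. Changes were smallest in exp 5 for HLA-DRB1 in its promoter group too (-0.02, against -4.12 in exp 3 and -5.28 in exp 8). So were those of GPC2 in the libraries labelled STAG3 promoter (-1.21, against -2.35 in exp 3 and -3.60 in exp 7). HLA-DRB1 with rs9270887 went the other way (-1.15, against -0.63 in exp 3 and -0.92 in exp 8). Whether repression was weaker in exp 5 was not tested.

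In the libraries labelled ZYX promoter, EPHA1 was lower and ZYX was not. All 4 libraries had EPHA1 below the mean of the other loci in their exp. A mislabelled library could lie below a mean too, so this does not exclude single mislabelled libraries. The change of EPHA1 was -3.00 on the log2 scale in exp 4 and -0.87 in exp 6. The region named ZYX promoter lies 27550 bp from the 5' end of ZYX, which argues against repression reaching EPHA1 from the ZYX start site. That holds only if these libraries carry the guides of the region deposited under their name. The coordinates go with exchanged names of the EPHA1 and ZYX guide regions. Each region holds the 5' end of the other gene and lies at least 27140 bp from that of the gene in its label. In the libraries labelled EPHA1 promoter, EPHA1 was at 1.34 against 6.48 CPM and ZYX at 203 against 227 CPM, neither past the threshold. The control means pool exps that this group does not share. Within exp 4, EPHA1 was at 2.02 against 4.51 CPM. The group held 3 libraries, of which 1 held 1593444 counts with EPHA1 at 0 CPM, so expression there neither showed nor excluded an exchange. No biological explanation was tested.

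With rs77972827, 4026 genes changed. The lower total of its exp 6 libraries was 15351009 counts, which argues against low depth, while lower complexity stays open, with 16231 and 14290 genes detected against 20169 and 21164 in exp 4 and TMM factors of 0.810 and 0.809. Repression of ZNF594 stays open too, as the ZNF594 promoter group changed 150 genes but 5 to 1274 with 1 library left out. The counts were 553 and 306 without exp 4, replicate 1 and 2, and 1274 and 5 without exp 6, replicate 1 and 2. The library whose loss left 5 genes stood apart from its exp (r = 0.935 with its median), and without it ZNF594 was still at -4.44. A difference carried by exp 6, which holds no control, stays open, as 19 genes changed without exp 5 and exp 6, a fit that drops 2 of the 4 libraries. An effect of the variant itself on distant genes was not tested.

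ANXA4 was at 7.89 ± 3.07 CPM in the control and 70.3 ± 9.59 CPM in the guide libraries. It was lower in the control in 4 of the 4 exps with controls, so control libraries of a single exp number do not account for it. As every control library lay below every guide library, that count was fixed and is no separate test. Repression at ANXA4 by the control guides and a wider difference in state cannot be told apart: 1473 genes differed between the control and the guide groups, and 1 gene of all tested was lower in every control library than in every guide library. The sequences of the control guides are not given in the sources used here. No biological explanation was tested.

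Each count of changed genes was set against 100 splits of the libraries of the group and the control, the real one included, with limma on log2 CPM after the exp effects were removed, so the real counts here differ from the edgeR counts of the report. As many genes were called in 1 to 4 splits in 22 of 25 comparisons, a share under 0.05. ANXA4, which parts every control library from every guide library, can by itself give the real split a call, so small counts say little. Chance cannot be excluded for the FCGR3B promoter group (6 splits; 11 genes against 607 in the highest other split) and rs12703526 (8 splits; 3 against 970). For the EPHA1 promoter group limma called 0 genes in the real split, so all 100 splits called as many by construction (the highest other 4), which says nothing about chance. In 4 splits for rs4575098 (3 against 1832) and rs6509201 (2 against 555) and in 3 splits for the APOE promoter group (123 against 2637), BIN1 (12 against 220), rs6979218 (4 against 30), rs72838287 (4 against 11) and rs72847948 (13 against 95), another split called more genes. Another split also did in 2 splits for STAG3 (10 against 109), ZNF594 (3 against 1925), rs12721109 (10 against 2314) and rs184017 (6 against 56). These counts, several times the real one, point to structure among the libraries, which are not exchangeable, so these splits do not show in any comparison that chance is excluded. In most of the 14 comparisons with such a split it set control libraries of exp 4 and exp 7 together, although the mean effects of the exp numbers had been removed; whether the structure follows the exp number was not tested. The real split was the highest of the 100 (1 split) for the promoter groups of ADAMTS4 (17 against 0), EXOC3L2 (1468 against 128), HLA-DRB1 (718 against 580), SPDYE3 (21 against 1) and ZYX (2441 against 24). It was so too for rs13230744 (75 against 1), rs28732235 (345 against 260), rs77972827 (3040 against 4), rs9270887 (64 against 27) and rs9271176 (812 against 1). For rs9271607 (1 against 0) the count rests on 1 gene.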

How the results depend on the processing

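Among the alternatives, leaving out 6 libraries whose profile stood apart from their exp and adding 3 surrogate variables were chosen after the results were seen, and the others were fixed before the data were examined. Of 407 results for targeted genes under an alternative or with a library left out, 360 kept their direction and their side of the threshold, 11 were no longer past it, 16 were newly past it and 20 changed sign. The threshold here was on p adjusted over all genes, which most targeted genes did not pass in the main fit. Most of the 360 thus stayed uncalled, and calls over the list alone were not judged here at that adjustment. Differences between variant and promoter groups were judged over the list alone. BIN1 and ZNF594 in their promoter groups kept direction and side under all 14 alternatives, BIN1 between -2.17 and -1.74 and ZNF594 between -6.43 and -4.45. With 1 library left out ZNF594 ran from -6.88, without exp 6 replicate 1, to -4.44. Of 287 differences between variant and promoter groups 278 kept both, and of 2703 results for genes named with a changed count 2033 did, 661 were no longer past the threshold, 5 were stronger and 4 changed sign. For the named genes this depended on the setting. Only 42 of 153 kept both against the other loci's libraries, 54 with libraries summed and 74 without exp 5 and exp 6. By contrast, 151 did with size factors by the median of ratios and 152 without the control libraries of exp 8. The counts of changed genes were the least stable: 277 of 444 moved by more than 1.5 times, and with size factors by the median of ratios all 25 stayed within that. For these changes the cause was not tested. A group left with 2 libraries was assumed to vary like the others. At these depths 34% of simulated 2-fold changes and 100% of 4-fold changes were recovered in a group of 4, so small changes are often missed. The simulated changes were in well-counted genes without exp effects, so these shares do not describe scarce genes or libraries that stand apart. SPDYE3 and EXOC3L2, at 0 counts, were not tested under any alternative.

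Targeted genes moved with the reference and with exp 5 and exp 6. ZYX in the libraries labelled ZYX promoter was no longer past the threshold with libraries summed (0.82), with the other loci as reference (0.45), without exp 5 and exp 6 (0.55) and without the control libraries of exp 4 (0.77). With a library left out it ranged from 0.65, without exp 6 replicate 2, where it also ended (adjusted p = 0.0687), to 0.85. ZNF594 with rs77972827 was no longer past it with libraries summed (-1.05), 3 surrogate variables (-0.46), without exp 5 and exp 6 (-0.54) and without the libraries standing apart (-0.40), and ranged from -1.35 to -0.73 with a library left out, ending without exp 6 replicate 1 (-0.73) or 2 (-0.92). APOE in its promoter group came past it with no filter (-0.92), surrogate variables (-0.91), without exp 5 and exp 6 (-1.003) and without the libraries standing apart (-0.86). Over 14 alternatives its adjusted p ran from 4.4e-05 to 0.646. APOE with rs12721109 came past it with no filter (-1.12), surrogate variables (-0.99) and without exp 5 and exp 6 (-1.06), and BIN1 with rs72838287 with surrogate variables (-0.75) and without exp 5 and exp 6 (-0.75). HLA-DRB1 in its promoter group came past it with no filter (-1.74), surrogate variables (-1.97), DESeq2 (-2.54) and without exp 5 and exp 6 (-4.59). With a library left out it ranged from -4.58, without exp 5 replicate 2, to -1.37. HLA-DRB1 with rs28732235 came past it with no filter (1.39) and without the libraries standing apart (1.59).

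Targeted genes changed sign at values near 0 or where the gene was scarce. STAG3 in its promoter group, at 0.01, turned to -0.023 with size factors by the median of ratios, -0.034 with surrogate variables, -0.24 without exp 5 and exp 6, -0.021 without the libraries standing apart, -0.15 and -0.043 without the control libraries of exp 4 and exp 8, and -0.078 with DESeq2. With a library left out it ranged from -0.19, without exp 5 replicate 2, to 0.19, and it was -0.098 without exp 7 replicate 2. ADAMTS4 with rs4575098, from 2 counts, turned to -0.84 with the other loci as reference, -0.14 and -0.60 without the control libraries of exp 3 and exp 8, and -0.23 with DESeq2. It ranged from -1.82, without exp 3 replicate 1, to 0.71 with a library left out. HLA-DRB1 with rs9271607 turned to -0.21 with surrogate variables, -0.45 without exp 5 and exp 6 and -0.34 without the libraries standing apart, and ranged from -0.46, without exp 6 replicate 1, to 0.96. HLA-DRB1 with rs72847948 turned to -0.028 with surrogate variables. Against its promoter group, EPHA1 with rs12703526 turned to 0.037 without exp 5 and exp 6. HLA-DRB1 with rs9270887 and rs9271176 came past the threshold against the promoter group without exp 5 and exp 6 (3.85 and 3.52), with DESeq2 (1.67 and 1.44) and without HLA-DRB1 promoter exp 5 replicate 2 (3.82 and 3.52), the highest of ranges that began at 0.56 and 0.32. Those for rs28732235 and rs72847948 ran from 2.54 to 5.95 and from 1.91 to 5.12, for FCGR3B with rs4575098 from 3.73 to 7.33, and for ZNF594 with rs77972827 from 3.40 to 5.83. HLA-DRB1 with rs9271607 was no longer past it without the libraries standing apart (1.34) and without exp 6 replicate 1 (1.25), and ranged up to 5.16. Among named genes, reported as rises, TYMS in the APOE promoter group turned to -0.029 against the other loci, and without exp 5 and exp 6 SV2C in the EPHA1 promoter group, S100A8 with rs77972827 and UQCR11 with rs9271607 turned to -0.046, -0.31 and -0.29. With libraries summed 14 in place of 25 nearby genes passed. The list tests gave 0 calls in place of 173 with an estimated correlation, 177 with a replicate block and 135 against the other loci, where 19 of the 173 called lists turned the other way. The cell cycle list turned to lower in 7 comparisons, past the threshold in the BIN1 promoter group (adjusted p = 0.0448), the SPDYE3 promoter group (0.00287) and rs6509201 (0.00595), and not in the ZNF594 promoter group (0.418), rs12703526 (0.943), rs184017 (0.891) and rs9271607 (0.131). Actin and focal adhesion turned in 7, phagocytosis and Fc receptors in 3 and immediate early genes in 2, none past it.

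Counts of changed genes that moved by more than 1.5 times are given by label, a gene for its promoter group and an rs number for its variant group. With every gene kept whatever its counts, the counts by label were ADAMTS4 259, APOE 751, BIN1 141, EPHA1 639, EXOC3L2 1036, FCGR3B 176, HLA-DRB1 521, SPDYE3 71, STAG3 80 and ZNF594 745. With guides at variants they were rs12703526 8, rs12721109 333, rs13230744 576, rs184017 64, rs28732235 930, rs4575098 17, rs6509201 21, rs72838287 12, rs72847948 139, rs9270887 135, rs9271176 575 and rs9271607 876, and 3 of the 25 counts were within 1.5 times their reported value. With no term for the exp number they were ADAMTS4 11, APOE 45, BIN1 5, HLA-DRB1 67, SPDYE3 4, STAG3 3 and ZNF594 745. The variant groups gave rs12721109 3, rs13230744 8, rs184017 4, rs6509201 2, rs72847948 4, rs9271176 39 and rs9271607 1584, and 11 of the 25 counts were within 1.5 times their reported value. In a fit with a replicate block in place of the exp number the counts were ADAMTS4 46, FCGR3B 19 and HLA-DRB1 317. For variants the counts were rs13230744 208, rs9270887 14 and rs9271176 411, and 19 of the 25 counts were within 1.5 times their reported value. With the libraries of a group and exp number summed they were ADAMTS4 4, APOE 38, BIN1 4, EPHA1 193, EXOC3L2 3, FCGR3B 3, HLA-DRB1 19, SPDYE3 3, STAG3 4, ZNF594 6 and ZYX 14. Among the variant groups they were rs12721109 4, rs13230744 3, rs184017 3, rs28732235 26, rs6509201 2, rs6979218 69, rs72838287 2, rs72847948 3, rs77972827 1495, rs9271176 8 and rs9271607 187, and 3 of the 25 counts were within 1.5 times their reported value. With the other loci's libraries as reference the counts were ADAMTS4 0, APOE 3, BIN1 1, EPHA1 926, EXOC3L2 28, FCGR3B 0, HLA-DRB1 1, SPDYE3 0, STAG3 1, ZNF594 8 and ZYX 32. Guides at variants gave rs12703526 0, rs12721109 1, rs13230744 1, rs184017 2, rs28732235 42, rs6509201 0, rs6979218 2934, rs72847948 0, rs9270887 0, rs9271176 0 and rs9271607 1617, and 3 of the 25 counts were within 1.5 times their reported value. The edgeR counts of 0 came with 973, 479, 1002, 324, 814, 468, 652 and 1111 genes at an unadjusted p under 0.05, in the same order. With 3 surrogate variables added they were ADAMTS4 35, APOE 28, EPHA1 9, FCGR3B 16, HLA-DRB1 43, SPDYE3 24, STAG3 27, ZNF594 54 and ZYX 770. By variant the counts were rs12703526 10, rs12721109 11, rs13230744 15, rs28732235 886, rs4575098 16, rs72838287 15, rs77972827 33, rs9270887 26, rs9271176 84 and rs9271607 82, and 6 of the 25 counts were within 1.5 times their reported value. Without exp 5 and exp 6 the counts were ADAMTS4 42, APOE 1521, BIN1 30, EPHA1 11, EXOC3L2 28, FCGR3B 30, HLA-DRB1 609, SPDYE3 32, STAG3 21, ZNF594 34 and ZYX 538. In the variant groups they were rs12703526 12, rs12721109 61, rs13230744 2277, rs184017 32, rs28732235 13, rs4575098 21, rs6509201 3, rs6979218 1545, rs72838287 8, rs72847948 39, rs77972827 19, rs9270887 63, rs9271176 621 and rs9271607 66, so that all 25 counts moved. Without the 6 libraries standing apart they were ADAMTS4 194, APOE 823, BIN1 90, EPHA1 4, EXOC3L2 1600, FCGR3B 36, HLA-DRB1 489, SPDYE3 23, STAG3 23, ZNF594 18 and ZYX 3412. With guides at variants they were rs12703526 10, rs12721109 125, rs13230744 972, rs184017 57, rs28732235 2229, rs4575098 16, rs6979218 22, rs72847948 48, rs77972827 15, rs9270887 27, rs9271176 587 and rs9271607 7, and 2 of the 25 counts were within 1.5 times their reported value. Without the control libraries of exp 3 the counts were ADAMTS4 9, FCGR3B 10 and ZNF594 68. The variant groups gave rs13230744 14, rs4575098 3, rs6509201 3, rs72838287 2 and rs9271607 252, and 17 of the 25 counts were within 1.5 times their reported value. Without the control libraries of exp 4 they were ADAMTS4 8, APOE 7, BIN1 9, EXOC3L2 35, HLA-DRB1 22, SPDYE3 6, ZNF594 15 and ZYX 232. For variants the counts were rs12721109 4, rs13230744 26, rs184017 9, rs28732235 69, rs6509201 2, rs72847948 7 and rs9271176 24, and 10 of the 25 counts were within 1.5 times their reported value. Without the control libraries of exp 7 the counts were APOE 69, BIN1 7, EXOC3L2 430, HLA-DRB1 43 and SPDYE3 5. Among the variant groups they were rs12703526 6, rs12721109 7, rs13230744 19, rs9270887 7 and rs9271176 83, and 15 of the 25 counts were within 1.5 times their reported value. Without the control libraries of exp 8 they were ADAMTS4 82, APOE 909, BIN1 87, EPHA1 235, FCGR3B 66, HLA-DRB1 439, SPDYE3 39 and STAG3 11. Guides at variants gave rs12721109 253, rs13230744 381, rs184017 29, rs4575098 14, rs6509201 9, rs6979218 144, rs72838287 7, rs72847948 30, rs9270887 8, rs9271176 553 and rs9271607 243, and 6 of the 25 counts were within 1.5 times their reported value. With the DESeq2 Wald test the counts were ADAMTS4 55, APOE 125, BIN1 76, EPHA1 2355, FCGR3B 82, SPDYE3 44, STAG3 25 and ZNF594 245. By variant the counts were rs12703526 89, rs12721109 77, rs184017 89, rs4575098 28, rs6509201 46, rs6979218 128, rs72838287 25, rs72847948 54, rs9270887 83 and rs9271607 210, and 7 of the 25 counts were within 1.5 times their reported value. The replicate block was an alternative only, although a part shared by libraries of 1 replicate number is not excluded. Of 256 pairs, 123 had a correlation over 0.1 and 29 one below -0.1, so positive values prevailed. Within exp 8 all 55 pairs had one over 0.1 (lowest 0.127), so libraries of 1 number deviated together there. In exp 4, 21 of 36 pairs had one over 0.1 and 5 one below -0.1, and in exp 7, 8 and 4 of 55. The replicate block turned STAG3 in its promoter group to -0.030.

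With each of 94 libraries left out in turn, 54 of 94 counts moved by more than 1.5 times. Ranges are given by label, then each such value with the exp and replicate left out. Ranges were BIN1 5 to 19, with 5 and 5 (exp 7, 1 and 2); EPHA1 3 to 1103, with 1091 and 1103 (exp 4, 1 and 2) and 3 (exp 6, 1); EXOC3L2 121 to 1020, with 156 and 121 (exp 6, 1 and 2) and 309 and 1020 (exp 8, 1 and 2). They were HLA-DRB1 18 to 238, with 18 and 39 (exp 8, 1 and 2); rs12721109 3 to 22, with 3 and 3 (exp 7, 1 and 2) and 4 (exp 8, 1); rs13230744 10 to 220, with 11 and 220 (exp 3, 1 and 2), 194 (exp 5, 2) and 10 and 13 (exp 7, 1 and 2). Next were rs184017 11 to 19, with 11 (exp 6, 2); rs28732235 29 to 663, with 29 (exp 6, 2); rs4575098 2 to 3, with 2 and 3 (exp 3, 1 and 2) and 3 and 2 (exp 7, 1 and 2). Others were rs6509201 3 to 6, with 3 and 3 (exp 6, 1 and 2); rs6979218 64 to 579, with 369 (exp 6, 1) and 579 and 64 (exp 8, 1 and 2); rs72838287 2 to 4, with 2 (exp 3, 2). Further ranges were rs77972827 894 to 5527, with 1478 and 894 (exp 6, 1 and 2); rs9270887 3 to 7, with 7 (exp 5, 2); rs9271176 29 to 131, with 131 and 81 (exp 3, 1 and 2) and 29 and 100 (exp 8, 1 and 2). Then came rs9271607 5 to 2440, with 797 and 1183 (exp 4, 1 and 2) and 5 and 2440 (exp 6, 1 and 2); SPDYE3 3 to 8, with 5 and 3 (exp 7, 1 and 2) and 4 and 8 (exp 8, 1 and 2); STAG3 4 to 23, with 4 (exp 5, 2) and 23 (exp 7, 1). Last were ZNF594 5 to 1274, with 553 and 306 (exp 4, 1 and 2) and 1274 and 5 (exp 6, 1 and 2); ZYX 282 to 1023, with 583 and 282 (exp 6, 1 and 2).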

Other observations

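The comparison of the control with the mean of the 25 guide groups, and its tests, were chosen after the results were seen. IL1RN and LDHA were lower in the SafeHarbor libraries (n = 8) than in the guide libraries, and HMOX1 was higher. In edgeR, 1042 genes were higher and 431 lower in the control. ANXA4, on chromosome 2 (69644425 to 69827100), was at 7.89 ± 3.07 CPM in the control and 70.3 ± 9.59 CPM in the guide libraries (log2 difference -3.12 ± 0.11, adjusted p = 3.9e-44). Its neighbours AAK1 and GMCL1 differed by -0.11 ± 0.10 and 0.11 ± 0.10 (adjusted p = 0.292 for each over the list alone). IL1RN, the interleukin 1 receptor antagonist, was 1.33 ± 0.15 lower on the log2 scale (adjusted p = 2.2e-10) and LDHA, the lactate dehydrogenase, 0.58 ± 0.09 lower (adjusted p = 4.3e-06). BIRC7, an inhibitor of apoptosis, NKAIN4, a partner of the sodium pump, and MMP17, a matrix protease, differed by -2.37 ± 0.41, -1.76 ± 0.30 and -1.13 ± 0.19. HMOX1, the haem oxygenase, was at 3150 ± 1140 CPM in the control and 1631 ± 836 CPM in the guide libraries (log2 difference 0.99 ± 0.17, adjusted p = 5.4e-05). HOXB7, a homeobox gene, was higher by 1.40 ± 0.21 (adjusted p = 3.0e-06).

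Of 31 cell cycle genes 19 were lower in the control (adjusted p = 6.0e-25; adjusted p = 0.170 with an estimated correlation), TYMS among them by -0.95 ± 0.19. The actin and focal adhesion list had 7 of 24 members lower (adjusted p = 1.2e-06; adjusted p = 0.382 with an estimated correlation). Immediate early genes had 4 of 14 lower, and phagocytosis and Fc receptors 4 of 18 (adjusted p = 3.1e-04 and 0.00225; adjusted p = 0.382 for each with an estimated correlation). These are the lists that rose in most guide comparisons, which all share the control libraries.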
